A study of Mus musculus with 4 samples.

How the data were processed

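PolyA-selected RNA from first pharyngeal arches was fragmented and reverse transcribed with random hexamers, per the labels' protocols, in 4 libraries, 2 of each genotype. The labels number the libraries 1 and 2 in each group and do not say that they came from separate embryos or litters. P-values therefore measure only the spread between these samples, which may in part be technical. The deposited values are a normalized signal per gene: per the file headers, reads were counted with featureCounts, and the values are those read counts divided by a size factor per library. The submitters' processing notes name fastp 0.21.0 and the mm10 build. The aligner, the annotation release, the strand setting and the tool that normalized the counts are not given in the sources used here.

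Dividing each column by its smallest positive value gave whole reads for 100% of the values, within 0.01 of a whole number. The size factors of the file, 1.348 and 0.9723 for wild-type and 0.9376 and 0.8248 for Wnt1-Cre;pMes-Bmp4, equalled median-of-ratios factors computed from those reads. Read totals were 47849092 and 33763574 in wild-type and 31404494 and 29607541 in Wnt1-Cre;pMes-Bmp4. The file listed 52459 genes, of which 16622 had no reads. Symbols of 26 rows had been turned into dates by a spreadsheet; 19 of these rows were tested and none was named.

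The main test was limma 3.58.1 in R 4.3.3, with a trend in the prior variance, on log2 of the value plus a pseudocount of 1, for the 16746 genes with a mean of at least 10 over the 4 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are Wnt1-Cre;pMes-Bmp4 minus wild-type. The fit had 2 residual degrees of freedom and 5.26 prior degrees of freedom, so calls depended on the spread borrowed across genes. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333.

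Gene lists, 33 in all, were fixed with the design before the data were examined, as were the test, the rule for naming genes and the alternatives not described as added. They cover BMP response, BMP pathway components, proximal and oral odontogenic, distal arch, endothelin and Dlx5/6, dorsal and maxillary, FGF, hedgehog, WNT, retinoic acid, crest mesenchyme, skeletal, matrix, cell cycle, p53, hypoxia and immediate early genes, markers of other cell types, Hox genes, Y-linked genes with Xist, mitochondrial transcripts and ribosomal proteins. Lists with at least 3 genes tested, 32 of them, were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives.

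Named genes were Bmp4, then the 10 with the largest change in each direction among those past the threshold, with a mean of at least 50 and both transgenic libraries on the same side of both wild-type libraries, leaving out predicted genes and pseudogenes. From each list, at most 6 members past the threshold were taken by smallest p, or the 2 with the smallest p where fewer passed. Genes of the lists outside this rule, such as Id3, Nog, Grem1, Smad6, Smad7, Hand2, Dlx5, Dlx6 and Fgf8, and the genes first named under other observations, were chosen after their values were seen. Values of some single genes that the rule would name are not reported here.

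Coordinates, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly that mm10 names, using the longest transcript of each gene. A length was found for 96.9% of the genes tested and 98.2% of the calls. The length correction took each library's deviation from the mean log2 value of each gene over the 4 libraries. A spline of this deviation on log2 transcript length, with 4 degrees of freedom, was subtracted from the library. It was fitted on genes with a mean of at least 50. A second version also used GC content. Both were added after seeing the data, and no other correction was tried. Other alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile and TMM scaling, limma without the trend or with robust hyperparameters, the replicate number as a block, each library left out, edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered reads, and other thresholds. On the recovered reads edgeR called 409 genes higher and 915 lower.

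The steps were tested on simulated data with 200 changed genes among 16746 and 3 draws. On average 43.3% of 2-fold and 93.7% of 4-fold changes were recovered, and 12.7 unchanged genes were called. A simulated length trend with a slope of -0.303 was reduced to -0.00226. A list shifted on purpose passed with the preset correlation, and with an estimated correlation its adjusted p averaged 0.32. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.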

Results

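RNA was sequenced from the first pharyngeal arch of mouse embryos, the paired outgrowth that forms the upper and lower jaw and the teeth. Embryos were collected at E9.5 to E9.75, with 25 to 27 somites. There were 2 groups of 2 libraries each. The wild-type group was compared with Wnt1-Cre;pMes-Bmp4, a genotype in which the Cre recombinase of the neural crest lineage switches on a Bmp4 transgene. The title of the series places the work in a mouse model of syngnathia, the fusion of the jaws, and in the early patterning of the molars. Wild-type libraries 1 and 2 held 47849092 and 33763574 reads assigned to genes, and Wnt1-Cre;pMes-Bmp4 libraries 1 and 2 held 31404494 and 29607541.

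Bmp4, the ligand carried by the transgene, was 3.94-fold higher in Wnt1-Cre;pMes-Bmp4 than in wild-type. Its normalized read count was 559.4 ± 173 (SD, n = 2) in wild-type and 2200 ± 644 (SD, n = 2) in Wnt1-Cre;pMes-Bmp4. The libraries read 681.7 and 437.1 in wild-type against 2656 and 1745 in the transgenic group. The log2 fold change was 1.98 ± 0.27 (SE), with a limma adjusted p of 0.0211. The gene lies on chromosome 14 at 46383520 to 46390669 of GRCm38, and reads of the transgene and of the endogenous gene were counted together as far as they share sequence. The call was lost without wild-type replicate 1, where the log2 fold change was 2.30 and the limma adjusted p 0.115, and without wild-type replicate 2, where they were 1.66 and 0.348.

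The comparison asks which genes of the arch differ between the genotypes. No group carried Wnt1-Cre alone or pMes-Bmp4 alone. Raised Bmp4 therefore cannot be told apart from other effects of the transgenes or of genetic background. RNA of the whole arch also cannot place a change in the neural crest. Of the BMP response list 7 of 15 genes tested were higher in Wnt1-Cre;pMes-Bmp4, and of the distal arch list 4 of 12. Of the dorsal and maxillary list 5 of 14 were lower and 1 was higher, and of the FGF response list 5 of 17 were lower. These 4 lists passed in camera with the preset correlation, and each had a camera adjusted p of 0.774 with an estimated correlation. Of 16746 genes tested, 498 were higher and 884 were lower at a limma adjusted p under 0.05, so that 64% of the calls were lower. At least 2-fold changes were seen in 93 of the higher and 470 of the lower genes. In all 1382 calls both transgenic libraries lay on the same side of both wild-type libraries, which was also so for 59.7% of all genes tested, where chance gives 33.3%. The counts depended on the library left out: without wild-type replicate 1 no gene passed (0 higher, 0 lower in limma, 3185 at an unadjusted p under 0.05), and without wild-type replicate 2 limma called 1 higher and 0 lower. Without Wnt1-Cre;pMes-Bmp4 replicate 1 the counts were 2675 higher and 2719 lower, and without replicate 2 they were 1201 and 1902.

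Long transcripts were lower in Wnt1-Cre;pMes-Bmp4 as a class. Among genes with a mean of at least 50, the median log2 fold change was 0.24 for transcripts of 1266 to 2007 bases and -0.56 for those of 6349 bases and more. In that longest bin 10 genes were higher and 424 lower. After a correction for transcript length, chosen after seeing the data, 110 genes were higher and 205 lower, and 283 of the 1357 calls with a known length were called again in the same direction. A correction for length and GC content, also chosen after seeing the data, gave 593 higher and 793 lower, and 768 of the calls were called again in the same direction. Libraries of 1 group also differed with length. Across 12178 genes, which are not independent replicates, Spearman's rho with transcript length was -0.394 for the difference between the groups, 0.284 for wild-type 2 minus wild-type 1 and -0.192 for Wnt1-Cre;pMes-Bmp4 2 minus 1. In the longest bin wild-type 2 exceeded wild-type 1 by 0.13, and Wnt1-Cre;pMes-Bmp4 2 minus 1 was -0.09.

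**Figure D1:**
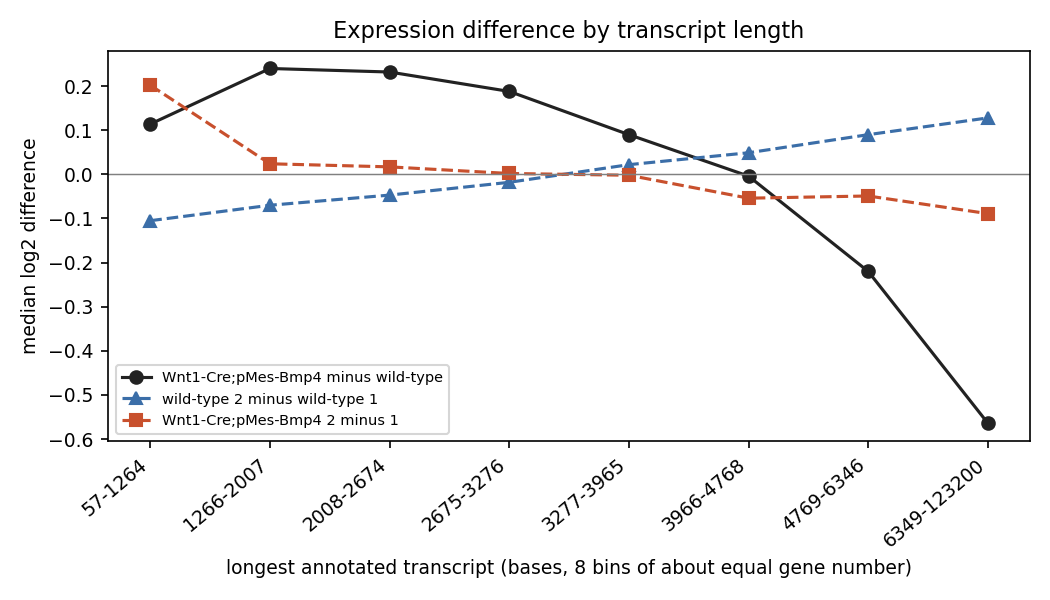
Median log2 difference (vertical axis) of genes in 8 bins of transcript length in bases (horizontal axis), for Wnt1-Cre;pMes-Bmp4 minus wild-type (black) and for the 2 libraries within each group (blue, wild-type; orange, Wnt1-Cre;pMes-Bmp4). The black line falls from 0.24 in the second bin to -0.56 in the longest bin, while both lines within groups stay between -0.11 and 0.20.

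The BMP response list rose. Of its 15 genes tested, 7 were higher, 0 were lower and 8 did not pass, with 9 higher when adjusted over the list alone; the median log2 fold change was 0.75. Camera gave an adjusted p of 1.85e-05 with the preset correlation, and the camera adjusted p was 0.774 with an estimated correlation. Bambi, a pseudoreceptor that dampens BMP signalling, rose from 1811 ± 228 to 6456 ± 622 normalized reads (SD, n = 2 each), a log2 fold change of 1.84 ± 0.15 (SE) with a limma adjusted p of 0.0182. Msx2, a homeobox gene downstream of BMP, rose 3.87-fold and Msx1 rose 2.24-fold, with limma adjusted p values of 0.0182 and 0.0297. The inhibitors of differentiation Id1, Id2, Id3 and Id4 rose with log2 fold changes of 0.60, 0.98, 0.75 and 1.08. The BMP antagonists Nog and Grem1 gave -0.07 and 0.26 and did not pass, nor did the inhibitory Smad6 at 0.38 and Smad7 at -0.21. After the length correction the list had a median of 0.53 and a camera adjusted p of 6.5e-05, and Msx1, Id1 and Id3 no longer passed, with log2 fold changes of 0.93, 0.39 and 0.53 and limma adjusted p values of 0.0756, 0.235 and 0.213.

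**Figure D2:**
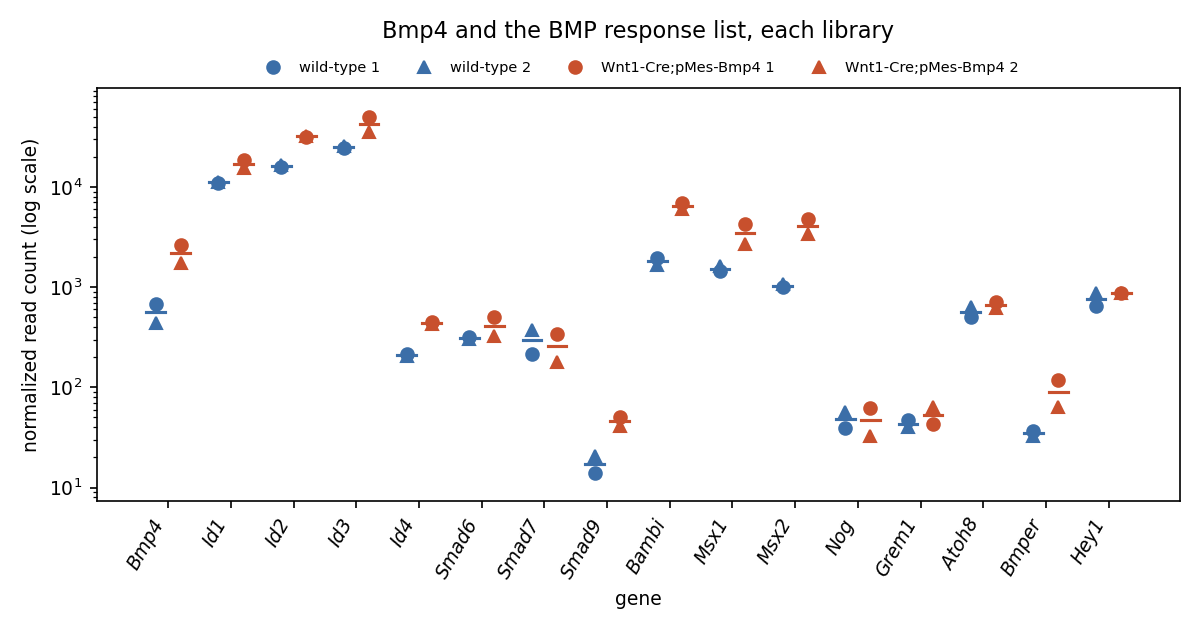
Normalized read count (log scale) of Bmp4 and the 15 tested genes of the BMP response list, with a point per library (blue, wild-type; orange, Wnt1-Cre;pMes-Bmp4; circles, replicate 1; triangles, replicate 2) and a bar at each group mean. Bambi lies at 1650 and 1972 in wild-type and at 6016 and 6896 in Wnt1-Cre;pMes-Bmp4.

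The distal arch program, which marks the tip of the arch near the midline, also rose. Of 12 genes tested, 4 were higher and 0 lower, with 6 higher when adjusted over the list alone, and the median log2 fold change was 0.73. The camera adjusted p was 0.0116 with the preset correlation and 0.774 with an estimated correlation, and it was 0.0622 without Wnt1-Cre;pMes-Bmp4 replicate 1. Msx1 and Msx2 belong to this list as well as to the BMP response. Gata3 rose 2.94-fold, from 162.9 ± 29.7 to 482.1 ± 91.9 normalized reads (SD, n = 2 each), and Isl1 rose 2.53-fold, with limma adjusted p values of 0.0233 and 0.0231. Hand2, a central distal regulator, was at 47.33 ± 4.39 and 51.64 ± 25 and did not pass (log2 fold change 0.04, limma adjusted p 0.962).

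The dorsal and maxillary program fell. Of 14 genes tested, 5 were lower, 1 was higher and 8 did not pass, with 7 lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.46, and the camera adjusted p was 0.00668 with the preset correlation and 0.774 with an estimated correlation. Pou3f3, a POU factor of the maxillary and proximal arch, was 22.9-fold lower, the largest fall among the genes named. It went from 673.4 ± 367 to 26.84 ± 8.8 normalized reads (SD, n = 2 each), with a log2 fold change of -4.52 ± 0.43 (SE) and a limma adjusted p of 0.0182. The orphan nuclear receptors Nr2f1 and Nr2f2 were 2.01-fold and 1.89-fold lower, and the Notch target Heyl was 3.69-fold lower. Alx1, a homeobox gene of the frontonasal and maxillary mesenchyme, rose 2.52-fold (limma adjusted p 0.0361). The wild-type libraries themselves differed in several of these genes. Pou3f3, Heyl and Nr2f1 were at 413.9, 117.9 and 2018 in wild-type 1 and at 932.9, 223.2 and 2925 in wild-type 2. Alx1 went the other way, at 788.5 and 425.8, and Nr2f2 was at 2836 and 3008. Whether the dissected tissue differed was not tested. After the length correction the list kept a camera adjusted p of 0.00579, while Alx1, Heyl and Pknox2 no longer passed in limma (adjusted p 0.07, 0.0569 and 0.0597). Their log2 fold changes went from 1.33, -1.89 and -0.61 to 1.13, -1.78 and -0.67.

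In the endothelin and Dlx5/6 ventral program, Dlx3 and Dlx4 fell and the other 9 of 11 genes tested did not pass; the count was the same, 2 lower, when adjusted over the list alone. The median log2 fold change was -0.40, with a camera adjusted p of 0.0178 with the preset correlation and 0.774 with an estimated correlation. Dlx4 was 3.62-fold lower and Dlx3 was 1.96-fold lower, with limma adjusted p values of 0.0286 and 0.0423. Dlx4os, a transcript antisense to Dlx4, was 5.74-fold lower, but the 2 loci overlap by 1212 bases and no source states that counting used the strand, so their values cannot be separated. Dlx5 and Dlx6 had log2 fold changes of -0.40 and -0.95 and did not pass (limma adjusted p 0.356 and 0.0895).

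The proximal and oral odontogenic program, which holds regulators of the tooth field, did not stand apart from other genes, with a camera adjusted p of 0.843. Of its 15 genes tested, 1 fell and 14 did not pass; adjusted over the list alone, 3 were higher and 1 was lower. The 1 that fell was Barx1, a homeobox gene of the proximal, molar-forming mesenchyme, on chromosome 13 at 48662998 to 48666507 of GRCm38. Its normalized read count went from 5180 ± 2370 to 1156 ± 652 (SD, n = 2 each), 4.62-fold lower, with a log2 fold change of -2.21 ± 0.43 (SE) and a limma adjusted p of 0.0321. After the length correction its log2 fold change was -2.43 and its limma adjusted p 0.051. Fgf8, a signal of the oral epithelium, had a log2 fold change of -0.55 ± 0.19 (SE) and did not pass, with a limma adjusted p of 0.115. Without Wnt1-Cre;pMes-Bmp4 replicate 1 the list passed in the lower direction, with a median of -0.42 and a camera adjusted p of 0.0287.

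The FGF response list fell. Of 17 genes tested, 5 were lower, 0 higher and 12 did not pass, with 6 lower when adjusted over the list alone. The median log2 fold change was -0.45, and the camera adjusted p was 0.000302 with the preset correlation and 0.774 with an estimated correlation. The feedback inhibitors Spry4, Spry2 and Spred2 were 2.84-fold, 2.54-fold and 2.32-fold lower, with limma adjusted p values of 0.0223, 0.0365 and 0.0239. The receptor Fgfr1 was 2.24-fold lower and Il17rd was 2.11-fold lower. Other members moved little and did not pass, with log2 fold changes of 0.01 for Etv5, -0.14 for Dusp4, -0.20 for Spry1 and -0.23 for Spred1. Of the 17 genes, 15 had a negative log2 fold change. The list also holds ligands and receptors, such as Fgf8 and Fgfr1. After the length correction the list kept a camera adjusted p of 0.00037, while Fgfr1 and Il17rd no longer passed in limma (adjusted p 0.0591 and 0.139), with log2 fold changes going from -1.17 and -1.07 to -0.98 and -0.58.

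**Figure D3:**
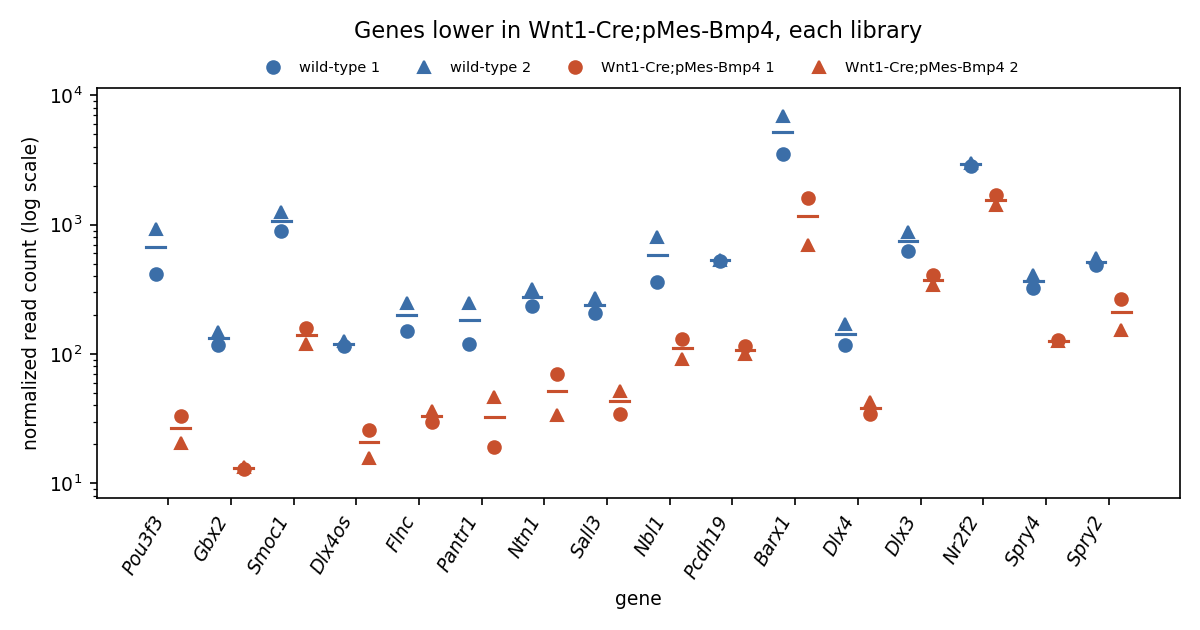
Normalized read count (log scale) of the 10 named genes with the largest falls and of Barx1, Dlx4, Dlx3, Nr2f2, Spry4 and Spry2, with a point per library (blue, wild-type; orange, Wnt1-Cre;pMes-Bmp4; circles, replicate 1; triangles, replicate 2) and a bar at each group mean. Pou3f3 lies at 413.9 and 932.9 in wild-type and at 33.06 and 20.61 in Wnt1-Cre;pMes-Bmp4.

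The hedgehog response, neural crest mesenchyme and extracellular matrix lists fell in the deposited values and did not pass after the length correction. They hold long transcripts, with medians of 4416.5, 5064 and 5564 bases. In the hedgehog list 3 of 12 genes were lower and 0 higher (5 lower and 1 higher when adjusted over the list alone). They were the receptor Ptch1 at 2.2-fold, the transcription factor Gli3 at 2-fold and Cdon at 2.12-fold lower. The list mixes pathway components with targets, so its fall does not give the direction of hedgehog signalling. Of the 12, 9 had a negative and 3 a positive log2 fold change. The positive ones included Foxf1 at 1.04 and Foxf2 at 0.48, which did not pass. Gli1, at -1.01, did not pass either (limma adjusted p 0.0646). The list's median log2 fold change was -0.44, the camera adjusted p 0.015 with the preset correlation and 0.774 with an estimated correlation, and the length-corrected camera adjusted p was 0.0958 at a median of -0.43, with limma adjusted p values of 0.144 for Ptch1 and 0.0879 for Gli3, at log2 fold changes of -0.54 and -0.51. In the crest list 2 of 17 genes were lower, Tfap2a and Foxc1, and 1 was higher, Prrx2, which rose 2-fold; adjusted over the list alone, 4 were lower and 1 was higher. Its median of -0.53 had a camera adjusted p of 0.0107 with the preset correlation and 0.774 with an estimated correlation, and the length-corrected camera adjusted p was 0.122 at a median of -0.13, with limma adjusted p values of 0.0379 for Tfap2a, 0.0702 for Foxc1 and 0.0807 for Prrx2, at log2 fold changes of -1.15, -0.81 and 0.77. The crest call was also lost without wild-type replicate 2 (camera adjusted p 0.0786) and without Wnt1-Cre;pMes-Bmp4 replicate 2 (0.172). In the matrix list 5 of 19 genes were lower, led by the fibrillin Fbn2 at 2.77-fold, and Postn, a matrix protein of mesenchyme, rose 1.68-fold; adjusted over the list alone, 7 were lower and 1 was higher. Its median of -0.63 had a camera adjusted p of 0.00908 with the preset correlation and 0.774 with an estimated correlation, and the length-corrected camera adjusted p was 0.253 at a median of -0.26, with limma adjusted p values of 0.0485 for Fbn2 and 0.0566 for Postn. Their log2 fold changes went from -1.47 and 0.75 to -0.84 and 0.96.

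Of 22 cell cycle genes tested, 6 were higher, 1 was lower and 15 did not pass, with 10 higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 0.31. The camera adjusted p was 0.000504 with the preset correlation, 0.774 with an estimated correlation and 0.00558 after the length correction. Cyclin genes Ccne2 and Ccnb1 rose 1.95-fold and 1.65-fold, and the replication licensing gene Mcm5 rose 1.53-fold, with limma adjusted p values of 0.0348, 0.0401 and 0.0343. Mki67, a proliferation marker with a long transcript, fell 1.66-fold (limma adjusted p 0.0268), and its log2 fold change was -0.14 after the length correction. No gene of the list passed in limma after that correction (0 higher, 0 lower), with log2 fold changes going from 0.60 to 0.67 for Mcm6, from 0.61 to 0.50 for Mcm5, from 0.96 to 0.80 for Ccne2 and from 0.72 to 0.51 for Ccnb1.

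Markers of other cell types were read as lists. Of 16 epithelium markers tested, the keratins Krt18 and Krt14 rose 1.83-fold and 1.97-fold and 14 did not pass, with 6 higher when adjusted over the list alone. The median was 0.42, with a camera adjusted p of 0.00597 with the preset correlation and 0.778 with an estimated correlation. The camera adjusted p was 0.017 after the length correction, and neither keratin then passed in limma (adjusted p 0.0793 and 0.101), with log2 fold changes going from 0.87 and 0.98 to 0.65 and 0.75. That call was lost without wild-type replicate 2 (camera adjusted p 0.0515) and without Wnt1-Cre;pMes-Bmp4 replicate 1 (0.0523). Of 13 erythroid markers, 5 were lower and 8 did not pass, with 6 lower when adjusted over the list alone. The median was -0.71, with a camera adjusted p of 0.00186 with the preset correlation and 0.774 with an estimated correlation. The embryonic globin Hbb-y fell 1.98-fold (limma adjusted p 0.0218), and globins took 2.28% and 2.12% of reads in the wild-type libraries against 1.25% in each transgenic library. Reads of the near-identical globin copies Hba-a1 and Hba-a2 could not be assigned with certainty. Markers of endothelium, myeloid cells, pharyngeal endoderm, cranial mesoderm and muscle, heart, cranial ganglia, neural tube, glial crest and the otic region did not pass, with camera adjusted p values of 0.124, 0.311, 0.509, 0.651, 0.915, 0.748, 0.885, 0.39 and 0.435. Endothelium markers passed in the higher direction without Wnt1-Cre;pMes-Bmp4 replicate 2 (camera adjusted p 0.0464), with no filter on low values (0.0325) and after the length and GC correction (0.0133). None of the 11 Hox genes of more posterior arches reached the minimum level (0 tested).

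Of 13 mitochondrial genes, 6 were lower and 7 did not pass, led by mt-Nd6 at 2.92-fold, and the median was -0.56; 6 were also lower when adjusted over the list alone. The camera adjusted p was 0.00827 with the preset correlation and 0.774 with an estimated correlation. Without Wnt1-Cre;pMes-Bmp4 replicate 1 the camera direction turned to higher (adjusted p 0.00444) at a median of -0.15. The 5 members with a positive log2 fold change, singled out after their values were seen, were mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd3. Their normalized read counts were 8860, 16100, 14900, 1010 and 546 in Wnt1-Cre;pMes-Bmp4 library 2. In the other 3 libraries they were at most 1380, 3460, 3000, 377 and 168, and their log2 fold changes between the groups, from 0.37 to 0.84, did not pass. Of 22 genes of the large ribosomal subunit, 6 were lower and 16 did not pass, with 15 lower when adjusted over the list alone and a median of -0.49. The camera adjusted p was 1.37e-05 with the preset correlation and 0.774 with an estimated correlation. Rpl14 fell 1.55-fold (limma adjusted p 0.0344).

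The other lists did not pass. Camera adjusted p values were 0.169 for BMP pathway components, 0.152 for the WNT response and inhibitors, 0.721 for WNT ligands and R-spondins, 0.798 for retinoic acid and 0.504 for chondrogenic and osteogenic genes. They were 0.435 for p53 targets, 0.39 for hypoxia and glycolysis, 0.588 for immediate early and heat shock genes, and 0.748 for Y-linked genes with Xist. Some of these lists passed under an alternative. The WNT response list passed in the lower direction without Wnt1-Cre;pMes-Bmp4 replicate 1 (median -0.48, camera adjusted p 0.0321), and BMP pathway components did so with no filter on low values (camera adjusted p 0.0407). The immediate early list passed in the higher direction without wild-type replicate 2 (camera adjusted p 0.0468) and without Wnt1-Cre;pMes-Bmp4 replicate 2 (4.09e-16), and in the lower direction without Wnt1-Cre;pMes-Bmp4 replicate 1 (0.00185). Single members still changed, and not only downward. The p53, hypoxia and WNT response lists each had 1 gene higher and 1 lower in limma. The BMP receptor Bmpr2 fell 3.16-fold and the signal transducer Smad5 fell 1.98-fold, and the ligand Wnt5a fell 2.03-fold, with limma adjusted p values of 0.0194, 0.0218 and 0.0218. After the length correction these 3 genes had limma adjusted p values of 0.0567, 0.0627 and 0.0672, and log2 fold changes that went from -1.66, -0.98 and -1.02 to -0.98, -0.61 and -0.61. Zmat3, a p53 target, fell 3.84-fold and passed both ways (limma adjusted p 0.0211 and 0.0401).

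**Figure D4:**
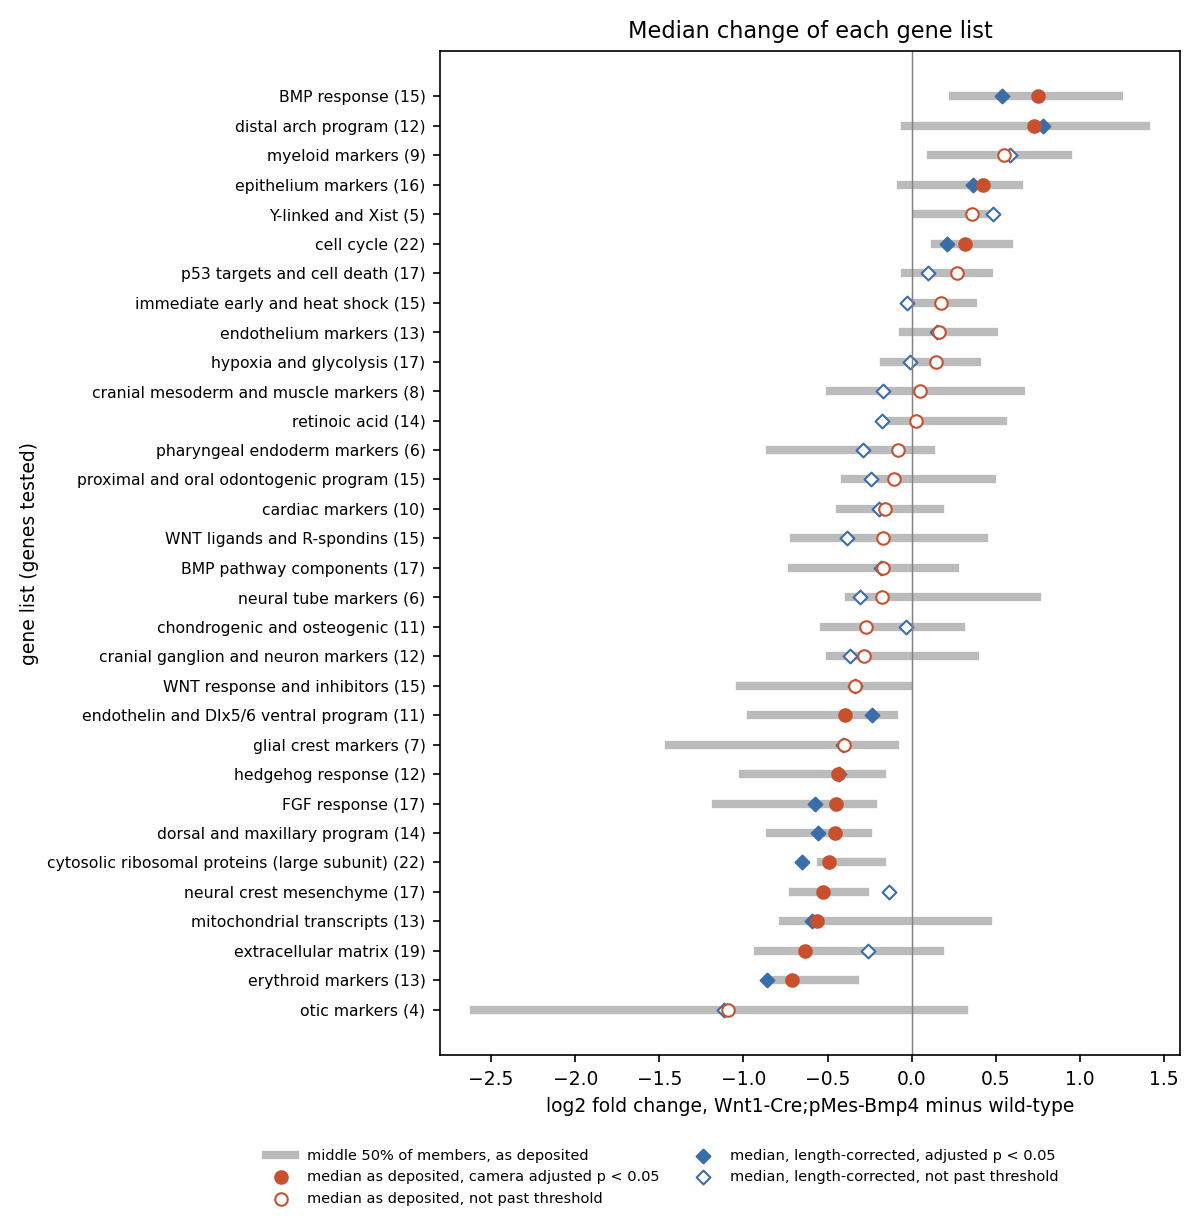
Median log2 fold change, Wnt1-Cre;pMes-Bmp4 minus wild-type (horizontal axis), of each list with its number of genes tested, as deposited (orange circles) and after the length correction (blue diamonds), filled where the camera adjusted p with the preset correlation was under 0.05; grey bars span the middle 50% of the members as deposited. The extracellular matrix median moves from -0.63 to -0.26 and the FGF response median from -0.45 to -0.58.

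The 10 genes with the largest rises, by the rule fixed for naming, were Nkx2-6, Pik3r2, Rxfp1, Masp1, Dkk1, Msx2, Sct, Bambi, Cd36 and Dok5. Nkx2-6, a homeobox gene of the pharyngeal region, rose 5.3-fold from a low level, 15.67 ± 6.16 to 84.97 ± 15.6 normalized reads (SD, n = 2 each), with a limma adjusted p of 0.0301. Dkk1, a secreted WNT inhibitor on chromosome 19 at 30545863 to 30549665, rose 3.91-fold, from 126.9 ± 35.5 to 490.1 ± 46 (limma adjusted p 0.0211). Pik3r2, a regulatory subunit of PI3 kinase, rose 4.47-fold and the relaxin receptor Rxfp1 rose 4.12-fold, with limma adjusted p values of 0.0237 and 0.0268. After the length correction 6 of the 10 passed in limma, and the largest adjusted p of the others was 0.0612. These others were Nkx2-6, Masp1, Sct and Cd36. Their log2 fold changes went from 2.406, 2.004, 1.942 and 1.695 to 2.196, 2.237, 1.820 and 1.590.

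The 10 with the largest falls were Pou3f3, Gbx2, Smoc1, Dlx4os, Flnc, Pantr1, Ntn1, Sall3, Nbl1 and Pcdh19. Gbx2, a homeobox gene, fell 9.38-fold, from 131.8 ± 21.7 to 13.07 ± 0.381 normalized reads (SD, n = 2 each), with a limma adjusted p of 0.0194. Smoc1, a secreted protein known to modulate BMP signals, on chromosome 12 at 81026808 to 81186414, fell 7.59-fold, from 1071 ± 263 to 139.5 ± 27.5 (limma adjusted p 0.0182). Nbl1, a secreted BMP antagonist of the DAN family, fell 4.9-fold, and the guidance cue Ntn1 fell 5.51-fold, with limma adjusted p values of 0.026 and 0.0233. Pantr1 is a noncoding transcript that neighbours Pou3f3 on chromosome 1, and it fell 5.62-fold. All 10 passed in limma after the length correction, with a largest adjusted p of 0.0497. Annotated antisense genes overlap Bmp4, Gbx2, Masp1, Nkx2-6, Ntn1, Pantr1, Pcdh19 and Pik3r2, and a same-strand gene overlaps Ntn1, Pou3f3, Rxfp1 and Smoc1, so reads of these loci may include those of the overlapping gene.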

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

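The length corrections and the crossed pairing were chosen after seeing the data; the other alternatives were fixed before. Bmp4 kept its direction in all 18 alternatives, with log2 fold changes from 1.66 to 2.30 and adjusted p values from 1.38e-29 to 0.348. It missed the limma threshold without the trend (1.98, adjusted p 0.145) and without either wild-type replicate. Counts of genes varied most. Limma without the trend called 0 higher and 0 lower, with 3925 at an unadjusted p under 0.05, where edgeR called 409 and 915. Robust hyperparameters gave 809 higher. Thresholds of 0.1 and of 2-fold gave 1307 and 1726, and 93 and 470. DESeq2 called 1284 higher and 1582 lower, sharing 1348 of the limma calls, with 3896 genes left without an adjusted p; edgeR shared 1271. The length correction gave 110 and 205, with fewer genes tested (16225), and turned the sign of 3 of the calls, none of which passed in the other direction or is named here. Length and GC together gave 593 and 793. Leaving out 1 library gave 0 to 2675 higher and 0 to 2719 lower; the library left alone in its group is then assumed to vary like the other pair, so the spread comes from that pair. TMM scaling gave 70.4% lower calls. With the replicate number as a block the counts were 165 higher and 543 lower; same-numbered libraries did not deviate together (correlation -0.147 across genes), so the numbers were not read as pairs. The crossed pairing as a block gave 1763 higher and 1952 lower.

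No list passed in either direction with an estimated correlation (0 higher, 0 lower) or with fry (0 higher, 0 lower), against 4 and 9 with the preset correlation; the smallest adjusted p was 0.774 and 0.109. In the simulation a truly shifted list had a camera adjusted p of 0.32 with an estimated correlation, averaged over 3 draws. Its genes were drawn independently of each other, so it cannot tell which correlation suits the real libraries. Leaving out 1 library gave 3 to 6 higher and 8 to 11 lower lists. Without Wnt1-Cre;pMes-Bmp4 replicate 1, the immediate early list reversed to a median of -0.56 and the mitochondrial list turned to higher in camera at a median of -0.15. Without replicate 2 of that group these medians were 0.94 and -1.03; the cause was not tested. Of 86 named genes called in limma, none reversed in any alternative, 43 passed after the length correction, 73 after that for length and GC, 62 with the block and 0 without either wild-type replicate. Only 43.3% of simulated 2-fold changes were recovered, so a gene that did not pass may still differ. Unchanged genes were called there above the nominal share, so some calls may be false.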

Other observations

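The tests of the length trend, of epithelium and of blood cells were chosen after the results were seen, and the rule that a correction must bring a median to at most 0.5 times its distance from 0 was added after the hedgehog value, which had counted for the length trend without it; the test of cholesterol synthesis and that over all chromosomes were written before their results, and the test over nuclear chromosomes was added afterwards.

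Idi1 and Msmo1, enzymes of cholesterol synthesis, rose 2.59-fold and 2.25-fold (limma adjusted p 0.0209 and 0.0194), which led to a list of the other enzymes and regulators. Of its 20 genes tested, 19 had a positive log2 fold change, 5 were higher and 0 lower, with 9 higher when adjusted over the list alone, and the median was 0.39. Camera gave p = 1.44e-06 with the preset correlation, p = 0.0343 with an estimated correlation, and p = 1.94e-06 after the length correction. These p values are unadjusted, so they cannot be set beside the adjusted values of the fixed lists. The list was prompted by genes of the same pathway in these same libraries, so its test is not independent of them. Acat2 and Insig1 had log2 fold changes of 0.82 ± 0.12 and 0.88 ± 0.17 (SE). As a hypothesis, sterol synthesis may be raised as a set in the transgenic arch; no technical explanation but transcript length was tested.

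The lower lists overlap with the length trend to different degrees. Random lists were matched on transcript length, GC and level, and each share counts the observed list in. For the FGF response list 0.22% had a median as low. This argues against the trend as its whole cause, since the median of the FGF list went from -0.45 to -0.58 after the correction. For the extracellular matrix list 10.7% of matched lists were as low and its median went from -0.63 to -0.26, so the length trend is a candidate explanation. For the hedgehog list 20.8% were as low, with a median of -0.44 before and -0.43 after. For the crest list 0.16% were as low, with a median of -0.53 before and -0.13 after. Neither list can be told apart from the trend, because the 2 measures point different ways. After the length and GC correction these medians were -0.227 and -0.19 (camera adjusted p 0.32 and 0.15). Called hedgehog members shrank with the length correction, such as Ptch1 from -1.14 to -0.54. Whether this ended the list's call was not tested. The genotype itself stays open as a cause of the trend, which lies between the groups and was not tested against RNA quality.

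For the rise of the BMP response list, no matched random list had a median as high in 10000 draws. The share is 0.01% with the observed list counted in, the smallest these draws can give. This argues against transcript length as its whole cause. A larger share of epithelium in the sample would raise no gene by more than the markers. The mean log2 fold change was 0.79 in the BMP list and 0.38 in the epithelium markers. A one-sided permutation test gave p = 0.0245, with genes as units, which are not independent replicates. The transgene, which the labels name, stays open, as do RNA quality, library preparation, dissection and other differences in tissue makeup, none of which was tested for this list.

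The erythroid fall was not shared by all markers of red cells. Globins fell by 0.92 on average over 7 genes and the other 6 markers had a mean of -0.25 (two-sided exact permutation p = 0.0152), and without the near-identical Hba-a1 and Hba-a2 p was 0.0476. The other markers were themselves uneven, among them Slc4a1 at -1.10, Klf1 at -0.38, Epor at -0.34, Gata1 at 0.13 and Alas2 at 0.36. The test took genes as units, and genes of red cells are not independent replicates. Slc4a1, which is not a globin, fell more than the globin mean. The test therefore cannot decide whether a lower share of blood cells was the cause. Transcript length is argued against, since no matched random list was as low. The share is 0.01% with the observed list counted in, the smallest the draws can give. Other causes were not tested.

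A passenger interval near an inserted transgene could gather the calls left after the length correction on 1 chromosome. Over all chromosomes, as that test was first written, the smallest adjusted p of one-sided Fisher's exact tests was 2.11e-07, for the mitochondrial chromosome with 7 of 16 genes called. That chromosome holds no inserted interval, so its value does not bear on the explanation. Over the nuclear chromosomes alone the smallest adjusted p was 0.183, for chromosome 18, where 16 of 432 genes were called, an odds ratio of 2.04 with an upper 95% limit of 3.41. An interval on a nuclear chromosome was therefore neither shown nor excluded.

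Xist was at 1158 and 5004 normalized reads in wild-type libraries 1 and 2, and at 995.1 and 817.2 in the transgenic libraries. The Y-linked Uty was at 535.5 and 227.3 in wild-type libraries 1 and 2, and at 537.5 and 630.5 in the transgenic libraries. In wild-type these 2 genes differed in opposite directions, which argues against 2 preparations of the same RNA for that pair. GC content followed the difference between the transgenic libraries across genes, with a Spearman rho of -0.483 over 12178 genes, which are not independent replicates.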
